A study of Mus musculus with 6 samples.

How the data were processed

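RNA sequencing was analysed from 6 libraries of subcutaneous B16F10 tumours, 3 labelled shControl and 3 labelled shSQLE. Groups and replicate numbers were taken from the titles the submitters gave. The authors deposited 1 table for the series with an expected count per gene and library, and this table was the starting point; reads were not analysed here. Per the submitters' processing notes, FastQC, STAR, RSEM and DESeq2 were used with the mouse build GRCm39, with no versions named. The annotation release, the settings of the aligner and whether counting used strand are not given in the sources used here. Expected counts, as RSEM estimates them, divide reads that match several genes or transcripts, so they need not be whole: between 11.4% and 12.7% of the deposited values above 0 in a library were not whole. Reads of paralogs, overlapping genes and antisense genes may therefore be shared, and genes named in the report whose values were not whole are marked there. The deposited table also lists a length and an effective length in bases per gene, which entered no test. Of 55349 genes, 1337 had no gene symbol. Per the labels' protocols, libraries were made from total RNA and sequenced as paired reads on a DNBSEQ-T7 instrument. No coordinates are given, since the annotation at hand was for another build.

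Total expected counts per library ranged from 16408622 to 19142185. Gapdh was the most abundant gene in all 6 libraries, and the 10 most abundant genes took 9.43% to 11.7% of a library. No pair of libraries was alike within sampling noise, so each counted as 1 replicate. Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 13268 genes holding 99.88% to 99.93% of the counts of a library. TMM factors ranged from 0.928 to 1.12. The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, glmQLFit with robust=TRUE and glmQLFTest) with group as the only term, on all 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is the fold divided by the square root of the quasi-likelihood F. Levels are given as TMM-normalised CPM (counts scaled to library size), and list means as the mean of log2 CPM with a prior count of 2. For single values an exact two-sided permutation test was used, which with 3 libraries against 3 cannot go below 0.1.

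A set of 36 gene lists (pathways, markers of cell types a subcutaneous tumour can hold, and 2 lists on RNA quality) was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, for lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the lists. List medians are over the edgeR fold changes unless called voom medians. For each list the number of members past the threshold is given over all genes and adjusted over the list alone. Named genes are Sqle, the genes with the largest changes among those past the threshold or, since fewer than 5 passed, the 10 with the smallest p, and from each list described the 2 members with the smallest p. Any other gene is said to be chosen after its values were seen. The tests, groups, lists, this rule and the alternatives named next were chosen before the data were examined.

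The alternatives were DESeq2 size factors, upper quartile scaling and library size alone; no filter and a filter of at least 1 CPM in 3 libraries; DESeq2 (version 1.42.0), limma voom and voom with quality weights as the test; robust=FALSE; an adjusted p of 0.1 and a minimum absolute log2 fold change of 1; named genes without mitochondrial and haemoglobin genes; the replicate number as a block; and each library left out in turn. For the lists, an estimated correlation, fry and camera on ranks were added. DESeq2 gave no adjusted p for 1050 genes, which were left as missing. Before use, the scripts were tested on simulated counts for shSQLE against shControl over 13065 genes, with 100 genes changed by each fold size and a separate list of 25 genes lowered 2-fold. For that comparison edgeR recovered 20% of genes changed 2-fold and 75% of those changed 4-fold, and of its 108 calls 3 were members of the lowered list and 10 were false. The lowered list had a camera p of 3.06e-20 and an unchanged one 0.576. The simulated genes were drawn independently of each other, whereas the type I interferon list had an estimated correlation of 0.80 in the data. The simulated shares and camera p may therefore be too favourable for these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.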

Results

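Gene expression was measured by RNA sequencing in 6 libraries from subcutaneous tumours of B16F10 cells, a pigmented mouse melanoma line that grows in C57BL/6 mice. Of these, 3 libraries came from tumours labelled shControl (replicates 1, 4 and 5) and 3 from tumours of the knockdown derivatives labelled shSQLE (replicates 1, 2 and 5). The targeted gene, Sqle, encodes squalene epoxidase, which oxidises squalene early in the sterol-specific part of cholesterol synthesis. A subcutaneous tumour holds melanoma cells together with host cells, and each library is a mixture of their RNA. Total expected counts were 16408622, 17596020 and 18587880 in shControl replicates 1, 4 and 5, and 19142185, 18826148 and 18790360 in shSQLE replicates 1, 2 and 5. After a filter on low counts, 13268 of the 55349 genes in the table were tested. The series has a single comparison, shSQLE against shControl, and asks how knockdown of Sqle alters expression in tumours growing in the animal. The labels do not say whether the replicates of a group are separate animals, so the p-values measure only the spread between these libraries, which may be technical.

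Sqle was lower in each shSQLE library than in each shControl library. It reached 148 ± 2.71 CPM (counts scaled to library size) in shControl (SD, n = 3) and 71.4 ± 5.24 CPM in shSQLE (SD, n = 3), which is 48.2% of the control level. Single libraries held 146, 151 and 148 CPM in shControl replicates 1, 4 and 5 and 70.4, 66.8 and 77.1 CPM in shSQLE replicates 1, 2 and 5, from 1250 to 2713 counts per library. The log2 fold change was -1.05 with an SE of 0.17 and a 95% confidence interval from -1.44 to -0.67. In edgeR's quasi-likelihood test the unadjusted p was 0.000173, the second smallest of all tested genes, and the Benjamini-Hochberg adjusted p was 0.9996. The two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 can give. DESeq2 put the same gene past the threshold, with a log2 fold change of -1.05 and an adjusted p of 8.15e-05.

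**Figure D1:**
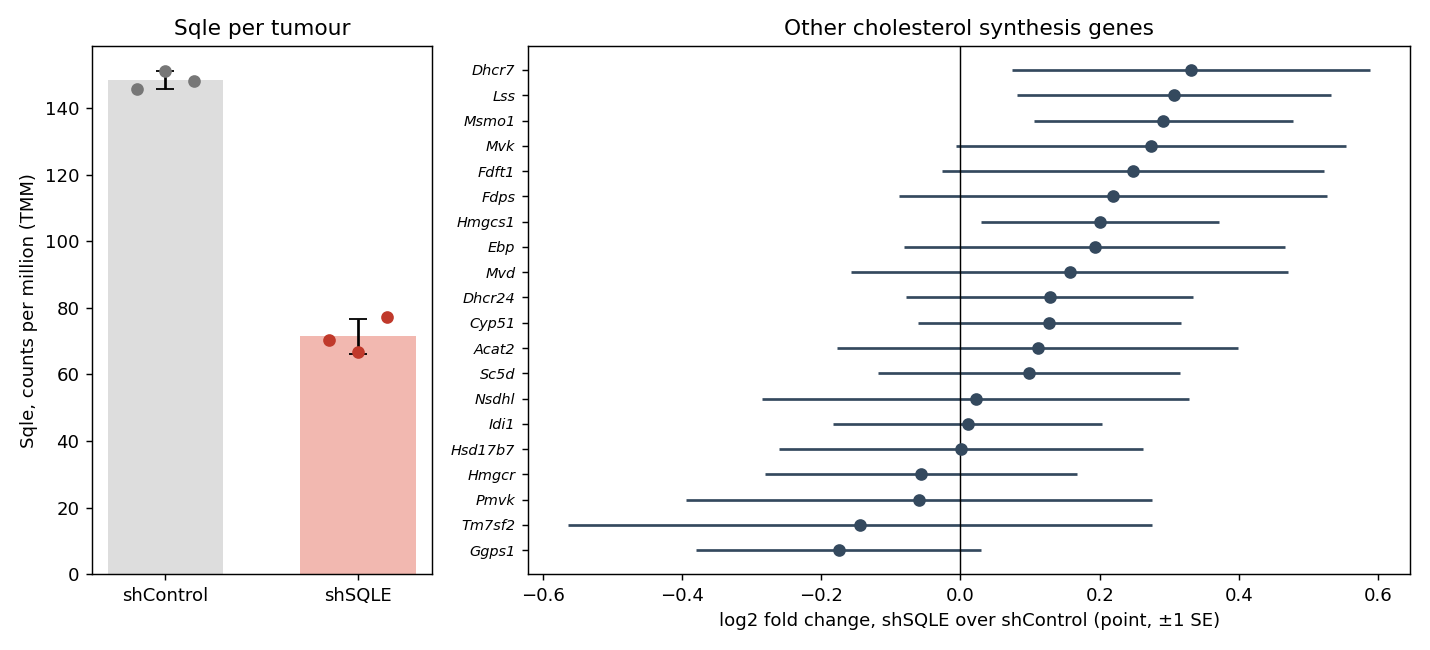
Sqle in each tumour library and the fold changes of the other cholesterol synthesis genes. Left, bars give the group mean of Sqle in TMM-normalised CPM, error bars the SD (n = 3) and points the libraries, with every shSQLE point below every shControl point. Right, points give the log2 fold change of shSQLE over shControl and lines ±1 SE for 20 genes, of which 16 lie above 0 and none passed the test across all genes.

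The 20 other enzymes of the cholesterol pathway showed small differences, most of them in the other direction, and the groups overlapped. The list means were 6.06, 6.55 and 6.47 log2 CPM in shControl replicates 1, 4 and 5. In shSQLE replicates 1, 2 and 5 they were 6.68, 6.42 and 6.36 log2 CPM (exact permutation p = 0.6). Of the 20 genes, 16 were higher and 4 lower in shSQLE, with a median log2 fold change of 0.13. None passed edgeR's test, over all genes or adjusted over the list alone. The members with the smallest p were Msmo1, a sterol C4-methyl oxidase, at 0.29 (SE 0.19), and Lss, lanosterol synthase, which acts directly after Sqle, at 0.31 (SE 0.23). As a group the list was higher against the other genes by camera with its preset correlation (adjusted p = 0.024), and this call was lost with an estimated correlation (adjusted p = 0.723 with an estimated correlation). Against a voom median of 0.13 with all libraries, it was also lost without shControl replicate 1 (camera adjusted p = 0.918, voom median 0.0017), without shSQLE replicate 1 (0.645, 0.035), with quality weights (0.278, 0.067) and with the macrophage list mean as a covariate (0.379, 0.058), the last chosen after seeing the data. The median was larger without shControl replicate 4 (0.27) and without shSQLE replicate 5 (0.21), and it was 0.071 with library size alone. The list of cholesterol uptake and SREBP control genes was not called (camera adjusted p = 0.786), with 5 of 16 members higher, and its direction turned without shSQLE replicate 5 (voom median 0.047 against -0.085). Its leading members were Mbtps1, the protease that first cleaves SREBP, at 0.35 (SE 0.19), and Srebf2, which encodes SREBP2, at 0.33 (SE 0.21). Fatty acid synthesis genes were lower by camera (10 of 14 members, median -0.16, adjusted p = 0.0113; adjusted p = 0.723 with an estimated correlation). Malic enzyme Me1 had a log2 fold change of -0.51 (SE 0.20) and the carboxylase Acacb one of -0.81 (SE 0.35), and 0 of the 14 passed over all genes or adjusted over the list alone. That call was lost without shControl replicate 5 (camera adjusted p = 0.223, voom median -0.098) and without shSQLE replicate 5 (0.606, -0.015). The voom median, -0.16 with all libraries, was -0.26 without shSQLE replicate 1, -0.25 without shSQLE replicate 2 and -0.26 with quality weights. This list and the adipocyte markers both had their highest mean in shControl replicate 5, 6.42 log2 CPM for fatty acid synthesis and 4.57 for adipocytes, but their lowest means were in different libraries, shSQLE replicate 5 and shSQLE replicate 1.

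Across the transcriptome, the spread between tumours of a group was wide, and 0 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 edgeR found 413 genes, 198 higher and 215 lower in shSQLE, where chance alone gives 663.4. The biological coefficient of variation was 30.4%, and the groups did not overlap for 855 genes, 6.44% of those tested, where chance gives 10%. DESeq2 called 8 genes and had 471 at an unadjusted p under 0.05. Limma voom called 0 (374 unadjusted), as did voom with quality weights (410 unadjusted). Leaving out shSQLE replicate 1 raised the edgeR count from 0 to 31 genes, 21 higher and 10 lower.

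**Figure D2:**
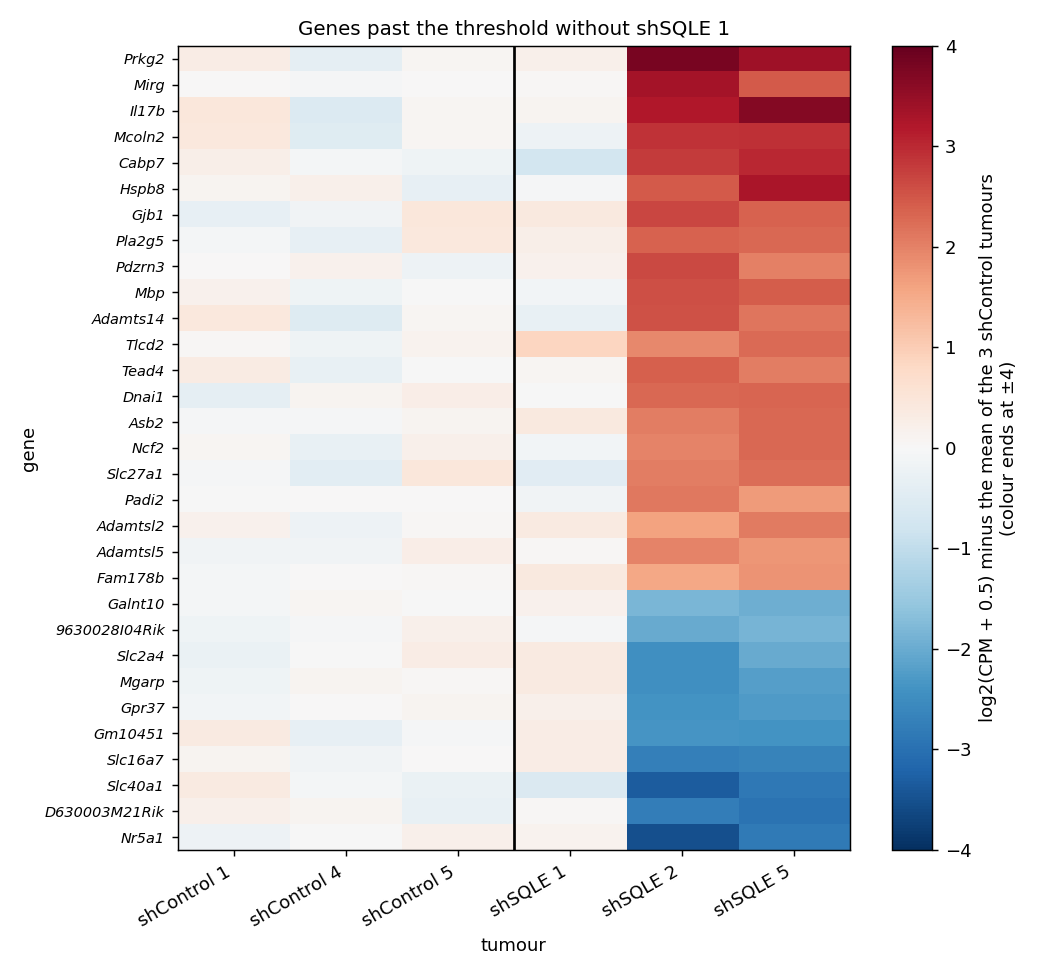
The 31 genes past the edgeR threshold when shSQLE replicate 1 is left out. Each cell is log2(CPM + 0.5) of a gene in a library minus the mean of the 3 shControl libraries (red higher, blue lower, colour ends at ±4), shControl left of the line and shSQLE right of it; shSQLE replicate 1 lies within the shControl range for 17 of the 31 genes.

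None of the 10 genes with the smallest p passed the edgeR test. Ccdc40, a protein needed to assemble motile cilia, had the smallest, with 6.05 ± 0.25 CPM in shControl and 20.2 ± 6.14 CPM in shSQLE (SD, n = 3 each) and a log2 fold change of 1.74 (SE 0.27). After Sqle followed Tlcd2 at 2.10 (SE 0.44), the heparan sulfate sulfotransferase Hs3st1 at 1.45 (SE 0.32), Mlip at 2.49 (SE 0.56) and Asb2 at 1.81 (SE 0.42). Mlip is a muscle protein and, like the markers of skeletal muscle, was highest in shSQLE replicate 5. The 2 did not follow each other elsewhere: Mlip was 1.12 CPM in shControl replicate 4 and 6.29 CPM in shSQLE replicate 2. The muscle list means there were 3.19 and 2.00 log2 CPM. Fam178b stood at 1.41 (SE 0.35) and the kinase gene Cdk18 at 1.68 (SE 0.42). Lower in shSQLE were Ifi44, an interferon-induced gene, at -2.99 (SE 0.71), and Podxl2, at -1.86 (SE 0.46). Expected counts of Podxl2 were not whole in every library, so some of its reads may be shared with other genes. Ifi44 was near the detection limit, at 2.17 ± 1.60 CPM in shControl and 0.265 ± 0.147 CPM in shSQLE (SD, n = 3 each). The 8 genes past the DESeq2 threshold were Ccdc40, Sqle, Tlcd2, Mlip, Asb2 and Hs3st1 from these, with Hspb8, a small heat shock protein (2.56 by DESeq2, adjusted p = 0.0493), and Rtp4, an interferon-induced gene (-2.65 by DESeq2, adjusted p = 0.0456).

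The type I interferon list had the smallest p of the 30 lists by camera with its preset correlation. All 25 tested genes of the type I interferon list were lower in shSQLE, with a median log2 fold change of -1.69, and 20 of them had an unadjusted p under 0.05. Over all genes 0 passed, and 16 passed when adjusted over the list alone, all of them lower. Irf9, a subunit of the transcription factor that type I interferon activates, stood at 25.6 ± 14.8 CPM in shControl and 10.4 ± 1.15 CPM in shSQLE (SD, n = 3 each), a log2 fold change of -1.30 (SE 0.38). The list mean was 2.64, 2.63 and 4.64 log2 CPM in shControl replicates 1, 4 and 5 and 1.62, 1.92 and 2.39 in shSQLE replicates 1, 2 and 5. These group means, 3.31 ± 1.16 and 1.98 ± 0.39 log2 CPM (SD, n = 3 each), did not overlap library by library and gave an exact permutation p of 0.1. Of the 30 lists 2 had groups that did not overlap, where chance gives 10%. Camera called the list lower (adjusted p = 9.45e-18), and the call was lost with an estimated correlation (p = 0.0906, adjusted p = 0.723 with an estimated correlation). With the preset correlation it was kept without each of the 6 libraries in turn, although without shControl replicate 5 the voom median went from -1.39 to -0.66.

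**Figure D3:**
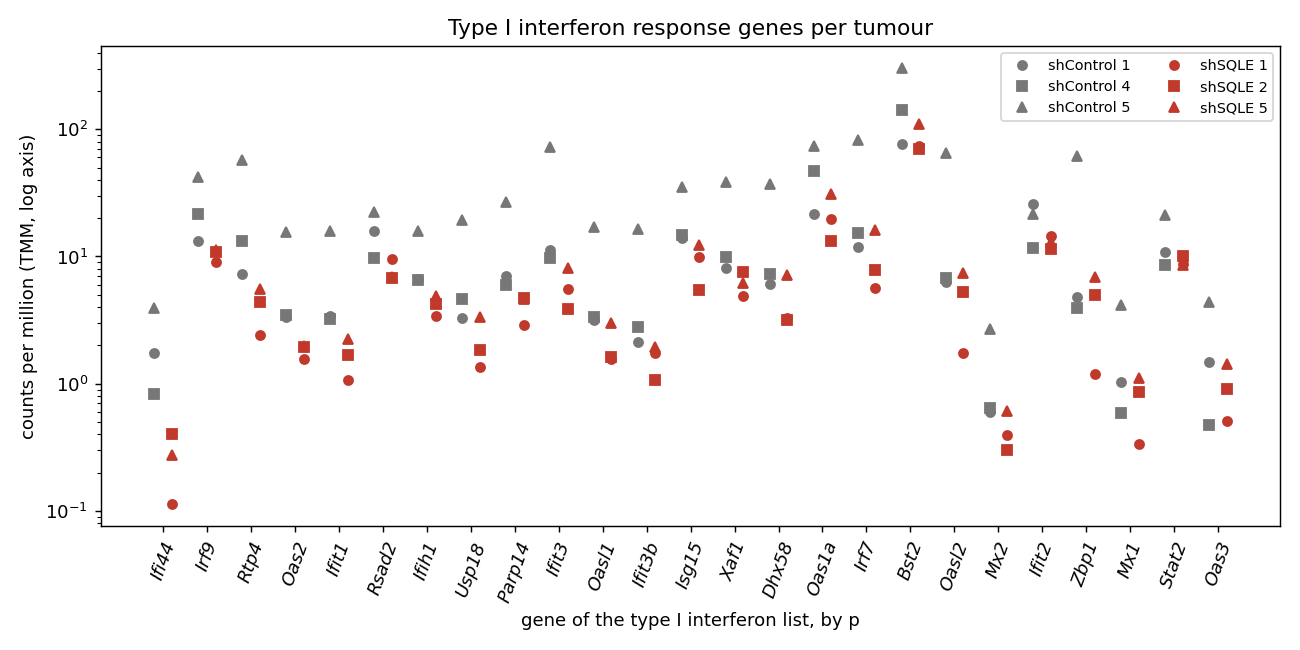
Type I interferon response genes in each tumour library. Each column is one of the 25 tested genes, ordered by p, and each point a library (grey shControl, red shSQLE) in TMM-normalised CPM on a log axis; shControl replicate 5 is the highest library for most genes, and the list mean of each shSQLE library is below that of each shControl library.

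The interferon-gamma, class I presentation and chemokine lists were also lower in shSQLE, and their means were highest in shControl replicate 5. Of the interferon-gamma targets, 22 of 23 were lower in shSQLE (median log2 fold change -1.40, camera adjusted p = 2.14e-05; adjusted p = 0.723 with an estimated correlation). Irf8, a transcription factor of myeloid cells, held 7.46, 6.61 and 25.7 CPM in shControl replicates 1, 4 and 5 and 5.07, 5.58 and 6.18 CPM in shSQLE replicates 1, 2 and 5. The guanylate-binding protein gene Gbp6, whose expected counts were not all whole, had a log2 fold change of -2.70 (SE 0.95). Of the class I presentation genes, 15 of 16 were lower (median -0.75, camera adjusted p = 0.000464; adjusted p = 0.723 with an estimated correlation). The heavy chain gene H2-K1 was at -1.33 (SE 0.37) and H2-T23 at -1.27 (SE 0.38), values that are uncertain because class I genes are near copies of each other. Chemokine genes were lower for 15 of 17 members (median -0.55, camera adjusted p = 0.0113; adjusted p = 0.723 with an estimated correlation), with Ccl7 at -1.27 (SE 0.63) and Cxcl9 at -1.90 (SE 0.99). In these 3 lists 0 genes passed over all genes or adjusted over the list alone. Without shControl replicate 5 all 3 calls were lost, each with a camera adjusted p of 0.789, and without shSQLE replicate 1 they were lost with 0.140, 0.116 and 0.884. The voom medians of the 3 lists, -1.07, -0.55 and -0.74 with all libraries, were -0.21, 0.021 and -0.31 without shControl replicate 5 and -0.48, -0.20 and -0.28 without shSQLE replicate 1. They were larger without shControl replicate 4 for class I genes (-1.02) and chemokines (-1.30), and without shSQLE replicate 5 for chemokines (-1.19). With the macrophage covariate, chosen after seeing the data, the chemokine call was lost (camera adjusted p = 0.494, voom median -0.21). The other 2 stayed past the threshold with smaller medians, -0.65 for the interferon-gamma list (0.00381) and -0.16 for the class I list (0.0463). Macrophage markers were also highest in shControl replicate 5 and lowest in shSQLE replicate 1, with list means of 3.74 and 1.26 log2 CPM.

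Markers of several host cell types were lower in shSQLE by camera, and the libraries within a group differed widely. Macrophage markers were lower for 20 of 21 genes (median -0.36, adjusted p = 0.00131; adjusted p = 0.723 with an estimated correlation), led by the mannose receptor Mrc1 at -0.96 (SE 0.62) and the scavenger receptor Cd163 at -1.12 (SE 0.78). Their list means were 3.05, 2.09 and 3.74 log2 CPM in shControl replicates 1, 4 and 5 and 1.26, 2.33 and 3.59 in shSQLE replicates 1, 2 and 5. Genes of alternatively activated macrophages, which include Mrc1 and Cd163, were lower for all 7 tested members (median -0.96, camera adjusted p = 0.00821; adjusted p = 0.723 with an estimated correlation), led by the eosinophil-associated ribonuclease Ear2 at -2.23 (SE 0.77). Fibroblast markers were lower for 16 of 17 genes (median -0.39, camera adjusted p = 0.0175; adjusted p = 0.731 with an estimated correlation), with Pdgfra at -1.37 (SE 0.59) and the matrix protein Lum at -1.03 (SE 0.88). Endothelial markers were lower for 15 of 16 genes (median -0.56, camera adjusted p = 0.000827; adjusted p = 0.723 with an estimated correlation), with the tight junction gene Cldn5 at -1.40 (SE 0.55) and Mmrn2 at -1.08 (SE 0.58). Adipocyte markers were lower for all 9 tested genes (median -2.04). Their camera adjusted p was 0.000122, and 0.723 with an estimated correlation. The fatty acid carrier Fabp4 was at -1.83 (SE 0.64) and hormone-sensitive lipase Lipe, whose expected counts were not all whole, at -1.27 (SE 0.53). In all 5 lists 0 genes passed over all genes or adjusted over the list alone.

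Each of these 5 calls was lost without at least one library, and the voom medians show by how much each list moved. For macrophages the median was -0.60 with all libraries, -0.23 without shControl replicate 5 (camera adjusted p = 0.721) and -0.0088 without shSQLE replicate 1 (0.929), where camera's direction turned. It was larger without shControl replicate 4 (-0.91) and without shSQLE replicate 5 (-1.27). For fibroblasts it was -0.70 with all libraries, -0.27 without shControl replicate 1 (0.260), -0.30 without shControl replicate 5 (0.704) and 0.089 without shSQLE replicate 1 (0.515), where the direction turned too. With the macrophage covariate, chosen after seeing the data, it was -0.035 (0.959). For endothelium it went from -0.46 to -0.17 without shControl replicate 1 (0.347) and to -0.29 without shSQLE replicate 1 (0.106), but to -0.89 without shControl replicate 4 and -0.72 without shSQLE replicate 2. For adipocytes it went from -1.88 to -0.96 without shControl replicate 5 (0.0538), to -4.26 without shControl replicate 4 (8.20e-16) and to -1.17 with the macrophage covariate (4.75e-07). For alternatively activated macrophages it was -1.02 with all libraries, and the call was lost without shControl replicate 5 (0.185, median -0.95), without shSQLE replicate 1 (0.166, -0.91), with quality weights (0.0591, -0.51) and with the macrophage covariate (0.186, -0.57). Without shControl replicate 4 that median was -1.79 (1.71e-07).

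**Figure D4:**
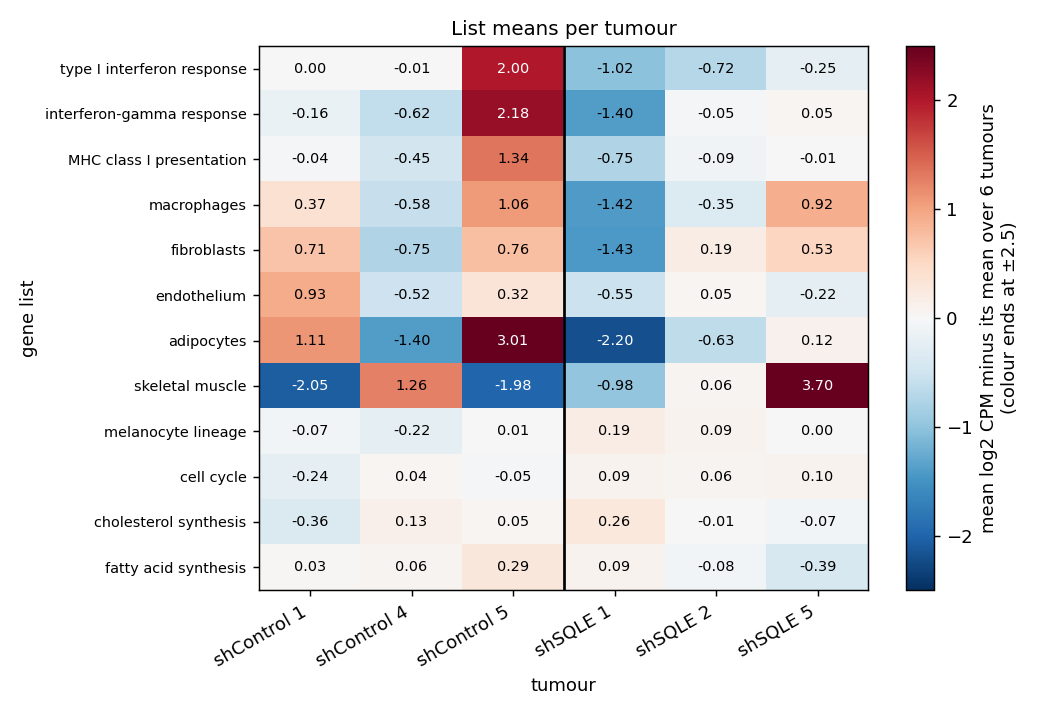
List means per tumour library for 12 gene lists. Each cell is the mean log2 CPM of a list in a library minus its mean over the 6 libraries (red higher, blue lower, colour ends at ±2.5), with shControl left of the line and shSQLE right of it. The type I interferon list reaches 2.00 in shControl replicate 5 and lies between -1.02 and -0.25 in the shSQLE libraries, and skeletal muscle reaches 3.70 in shSQLE replicate 5.

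Skeletal muscle markers were higher in shSQLE for 14 of 15 genes (median log2 fold change 2.99, camera adjusted p = 4.57e-05; adjusted p = 0.723 with an estimated correlation), and 0 passed edgeR's test over all genes or adjusted over the list alone. The calcium pump Atp2a1 was at 3.62 (SE 1.54) and the myosin heavy chain Myh4 at 4.84 (SE 2.11). The markers were unevenly spread in both groups, with list means of -0.12, 3.19 and -0.05 log2 CPM in shControl replicates 1, 4 and 5 and 0.96, 2.00 and 5.63 in shSQLE replicates 1, 2 and 5, and shSQLE replicate 5 had the highest level for 14 of the 15 markers. Acta1, skeletal muscle actin, reached 645 CPM there against at most 82.7 CPM in the other libraries, and was named after its values were seen. Without shSQLE replicate 5 the camera adjusted p of the list was 0.0755 and its voom median 0.57, against 2.31 with it, 1.40 without shControl replicate 5 and 3.78 with the macrophage covariate.

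Lists on pigment cells, proliferation, hypoxia and RNA quality showed smaller differences. Melanocyte lineage genes were higher for 15 of 20 members (median log2 fold change 0.15, camera adjusted p = 0.00821; adjusted p = 0.723 with an estimated correlation). Rab32, which directs cargo to melanosomes, was at 0.92 (SE 0.27), and Gpnmb, a melanosomal glycoprotein that macrophages also express, at 0.83 (SE 0.40). Cell cycle genes were higher for 21 of 25 members (median 0.16, camera adjusted p = 0.000827; adjusted p = 0.723 with an estimated correlation), led by the replication helicase subunits Mcm2 at 0.45 (SE 0.21) and Mcm5 at 0.43 (SE 0.22). The cell cycle list means of the groups, 6.93 ± 0.14 and 7.09 ± 0.02 log2 CPM (SD, n = 3 each), did not overlap library by library (exact permutation p = 0.1). The margin was narrow, with 7.05 in shControl replicate 4 and 7.07 in shSQLE replicate 2. Of the 30 lists 2 did not overlap, where chance gives 10%. Hypoxia and glycolysis genes were lower for 19 of 21 members (median -0.20, camera adjusted p = 0.00821; adjusted p = 0.723 with an estimated correlation). Its leading members went both ways, with Ndrg1 at 0.76 (SE 0.39), whose expected counts were not all whole, and Ero1a at -0.62 (SE 0.32). Transcripts of the mitochondrial genome were lower for all 9 tested genes (median -0.33, camera adjusted p = 0.00272; adjusted p = 0.723 with an estimated correlation), with mt-Nd3 at -0.66 (SE 0.27) and mt-Nd4l at -0.66 (SE 0.33). All genes with a mitochondrial genome symbol, also those outside the list such as mt-Rnr2, made up 2.76%, 2.05% and 2.98% of the counts in shControl replicates 1, 4 and 5. In shSQLE replicates 1, 2 and 5 they made up 1.79%, 3.19% and 0.945%. Immediate early and heat shock genes, which respond to handling of tissue, were higher for 10 of 15 members (median 0.19, camera adjusted p = 0.024; adjusted p = 0.723 with an estimated correlation), with Hsph1 at 0.49 (SE 0.25) and Hspb1 at 1.57 (SE 0.84). In these 5 lists 0 genes passed over all genes or adjusted over the list alone.

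Each of these 5 calls was lost without at least one library. For the melanocyte lineage the voom median was 0.15 with all libraries, 0.098 without shControl replicate 4 (camera adjusted p = 0.0558), still 0.15 without shSQLE replicate 1 (0.262) and 0.088 with library size alone. For the cell cycle it went from 0.17 to 0.083 without shControl replicate 1 (0.0607), to 0.27 without shControl replicate 4 and to 0.11 with quality weights or library size alone. For hypoxia it was -0.20 with all libraries, -0.18 without shControl replicate 1 (0.323), -0.15 without shSQLE replicate 5 (0.149) and -0.11 with quality weights (0.0554), but -0.34 without shControl replicate 4 and -0.34 without shSQLE replicate 1. For the mitochondrial genome it went from -0.41 to -0.23 without shControl replicate 5 (0.0584) and to -0.030 without shSQLE replicate 5 (0.650), but to -0.73 without shSQLE replicate 2. For immediate early genes it was 0.19 with all libraries, -0.057 without shControl replicate 4 (0.793), 0.055 without shSQLE replicate 2 (0.550) and 0.18 without shSQLE replicate 5 (0.105), and it was 0.29 to 0.45 without each of the other 3 libraries.

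Of the 36 gene lists, 30 had at least 5 tested members, and camera with its preset correlation called 17 of them, 5 higher and 12 lower. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.723, and fry called 0, the lowest adjusted p being 0.878. None of the 30 had an unadjusted p under 0.05 in either of those tests.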

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

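The macrophage covariate, leaving out both libraries numbered 5, leaving out the muscle list and not rounding were chosen after seeing the data. The edgeR count of 0 genes stayed at 0 in 20 alternatives, with a smallest adjusted p of 0.0831 when no filter was used. It became 8 with DESeq2 (6 higher, 2 lower), and it ranged from 0 to 31 when each library was left out in turn, 31 being without shSQLE replicate 1. With the replicate block it became 41 genes (5 higher, 36 lower), of which 1 was among the 8 of DESeq2 and 0 among the 31. Only the numbers 1 and 5 occur in both groups, so shControl replicate 4 and shSQLE replicate 2 add nothing to the block's contrast. Its counts and p-values thus rest on the libraries numbered 1 and 5. Deviations of those libraries from the group means correlated at -0.13 and 0.07 across genes. Nothing in the labels pairs the samples, so the block was not used elsewhere. Sqle stayed lower in all alternatives, from -1.005 to -1.107 with single libraries left out, and passed the threshold in DESeq2 alone (-1.05, adjusted p = 8.15e-05; -0.995 and 0.189 with the replicate block). The 17 called lists became 0 with an estimated correlation and 0 with fry, and ranged from 8 to 19 with single libraries left out, 8 both without shControl replicate 5 and without shSQLE replicate 1; the other alternatives stayed within 1.5 times. Among the 17 called lists the direction turned for fatty acid synthesis (0.072), skeletal muscle (-0.043) and the mitochondrial genome (0.20) with both libraries numbered 5 left out, for macrophages (-0.0088, range with single libraries left out -1.27 to -0.0088) and fibroblasts (0.089, range -1.003 to 0.089) without shSQLE replicate 1, for macrophages (0.081, their own mean being the covariate) and fibroblasts (-0.035) with the macrophage covariate, and for immediate early genes (-0.25) with the replicate block. Among the lists not called, it also turned, for example, for class II presentation (0.36) and sterol efflux (0.022) without shControl replicate 5, and for erythroid genes (-0.38) without shSQLE replicate 1. The replicate block called class II presentation (adjusted p = 9.91e-10), erythroid (5.56e-09) and sterol efflux genes (0.037), and the melanocyte lineage lost its call (0.133). These are voom medians, and the sign of camera's test decided the direction. The type I interferon list kept its call in the other 15 settings with a preset correlation or ranks. The cause was not tested for any of these. Genes with few counts are the least precise at these depths.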

Other observations

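The remaining lists were not called by camera with all 6 libraries. Class II presentation genes were lower for 9 of 10 members (median log2 fold change -1.07, camera adjusted p = 0.0747). Among them H2-DMb1 was at -0.86 (SE 0.32) and H2-DMa, whose expected counts were not all whole, at -1.19 (SE 0.82). This list depended on single libraries: camera called it lower on ranks (adjusted p = 0.0442), with quality weights (0.00127) and in 4 of the 6 fits that left out a library (0.000543 to 0.0251), while without shControl replicate 5 its direction turned (voom median 0.36 against -0.60, adjusted p = 0.247) and without shSQLE replicate 1 the median was 0.055 (0.937). Erythroid genes were higher for 8 of 9 members (median 1.05, camera adjusted p = 0.0798), and the alpha globin gene Hba-a1, a near copy of Hba-a2, held 11971 CPM in shSQLE replicate 1 against 1291 to 3217 CPM in the other libraries. Camera called the erythroid list higher on ranks (adjusted p = 0.0407), with library size alone (0.0284), with quality weights (0.0208) and in 3 of the 6 fits that left out a library (7.14e-06 to 0.0185). Without shSQLE replicate 1 its direction turned (voom median -0.38 against 0.56, camera adjusted p = 0.104), and without shControl replicate 5 the median was 0.070 (0.862). Genes of the unfolded protein response were higher for 13 of 20 members (median 0.08, camera adjusted p = 0.0907), and the list was called with quality weights (0.00102) and without shControl replicate 1 (1.10e-05). Among them Asns, asparagine synthetase, was at 0.74 (SE 0.22), with 170, 172 and 167 CPM in shControl replicates 1, 4 and 5 and 217, 289 and 343 CPM in shSQLE replicates 1, 2 and 5. Sterol efflux genes and liver X receptor targets were lower for 6 of 10 members (median -0.35, camera adjusted p = 0.418; voom median 0.022 without shControl replicate 5 and 0.045 without shSQLE replicate 1, against -0.24), with the exporter Abca1 at -0.72 (SE 0.51). Of the nerve and Schwann cell genes 4 of 7 were higher (median 0.83, camera adjusted p = 0.428), and 2 passed when adjusted over the list alone, 0 over all genes. These were L1cam at 3.02 (SE 0.82) and Mbp at 2.02 (SE 0.59), both higher in shSQLE replicates 2 and 5 than in the other 4 libraries. The direction of this list turned without shSQLE replicate 2 (voom median -0.21 against 0.46), without shSQLE replicate 5 (-0.15) and without shControl replicate 4 (-0.051).

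Lymphocyte markers were close to the detection limit. Of 22 T cell genes 6 were tested, with a median log2 fold change of -0.13, a mean of 0.03 and an upward camera test (adjusted p = 0.786). Lat, an adaptor of T cell receptor signalling, was higher at 1.75 (SE 0.54), while the receptor chain Trbc2 was at -0.73 (SE 0.69). B and plasma cell genes had 6 tested members (median -0.20, camera adjusted p = 0.994), neutrophil genes 6 (median 0.01, 0.786) and mural cell genes 9 (median -0.39, 0.666). Without shSQLE replicate 2 neutrophil genes, then 10, were called higher (camera adjusted p = 0.0129, voom median 0.45 against 0.051), and their direction turned without shControl replicate 4 (-0.41) and without shSQLE replicate 5 (-0.34). Mural cell genes were called lower without shControl replicate 4, with 11 tested members (camera adjusted p = 0.0223, voom median -0.56 against -0.38) and, in a fit chosen after seeing the data, with both libraries numbered 5 left out (0.0459), and their direction turned without shControl replicate 1 (voom median 0.010). Dendritic cell genes had 5 tested members with a median of -0.12, a mean of 0.15 and an upward camera test (adjusted p = 0.479). NRF2 and ferroptosis genes had 15 with a median of 0.01, a mean of -0.10 and a downward camera test (0.939), and p53 targets had 14 with a median of 0.01 (0.351). The p53 list was called higher without shControl replicate 4 (camera adjusted p = 0.0109, voom median 0.14 against 0.015), and camera's direction turned without shControl replicate 1 (0.998). Camera's direction for the T cell, B and plasma cell, dendritic cell and NRF2 lists also turned when single libraries were left out. Too few members were tested for cytotoxic effectors (1 of 15, Nkg7, at -1.54). The same held for genes linked to T cell inhibition (3 of 11, Lag3 at -0.56, Havcr2 at -0.13 and Entpd1 at 0.02). It also held for regulatory T cells (2 of 8, Ikzf2 at -0.77 and Tnfrsf18 at -0.27) and keratinocytes (2 of 15, Sbsn at -1.28 and Sfn at -0.31). No gene was tested of 11 for natural killer cells or of 11 for mast cells and eosinophils.

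Several of the tests reported next were chosen after the results were seen. These were the tests on the interferon list, both on a mislabelled library and those on host tissue in the 31 genes. The reading of the host cell test of the similar pair was also chosen then. The other splits of the samples were set out before, but the fit without shSQLE replicate 1 was picked for them after its calls were seen.

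The type I interferon list was lower in each shSQLE library, with a voom median log2 fold change of -1.39. A difference remained without the single high library, shControl replicate 5, where the median was -0.664 and 24 of 25 genes were still lower. Each shSQLE list mean stayed below those of shControl replicates 1 and 4, and camera with its preset correlation kept the call (adjusted p = 3.16e-09). The genes of the list move together (estimated correlation 0.80 with all libraries), and this fit was not repeated with an estimated correlation. Whether the remaining difference exceeds chance is thus not decided. Fewer macrophages in the shSQLE tumours cannot be told apart from another source: with the macrophage list mean as a covariate camera kept the interferon call (adjusted p = 2.40e-13, voom median -1.01) while the alternatively activated macrophage, fibroblast, chemokine and cholesterol synthesis calls were lost, but the difference of the list mean was -0.985 (SE 0.611) with it and -1.33 (SE 0.705) without, within 2 SE of 0 in both, and the camera call with all libraries was lost with an estimated correlation. Of the 10 splits of the 6 libraries 1, the real one, gave as large a difference (1.33, highest other 1.17), and 10 splits are too few for a share under 0.05. The list was also picked for its camera p in the real split, the smallest of 30 lists, which favours that split. An effect of Sqle knockdown on interferon signalling in the melanoma cells or in host cells may be involved, and was not tested.

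shControl replicate 4 and shSQLE replicate 1 were the most alike of the 15 pairs of libraries although they belong to different groups (Pearson r = 0.986 across genes, which are not independent replicates, next pair 0.966). A mislabelled library is argued against, since Sqle in shSQLE replicate 1 was 75.2 CPM below the lowest shControl library. The pair had the lowest mean scores of host cell markers (-0.62 and -1.13), so both tumours holding few host stromal cells stays open. Over 65 genes of the melanocyte lineage, cell cycle and cholesterol synthesis lists its median absolute log2 difference of 0.165 was 0.00652 (bootstrap SE 0.0343) above that of the closest other pair, a tie that does not decide. A biological explanation was not tested.

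Without shSQLE replicate 1, edgeR called 31 genes that follow shSQLE replicates 2 and 5. shSQLE replicate 1 was within the shControl range for 17 of them. It lay on the same side of the shControl mean as shSQLE replicates 2 and 5 for only 14 of the 31. Examples of the 31 genes, chosen after their values were seen, are Mbp and Gpr37. The myelin gene Mbp held 81.5, 64.7 and 71.8 CPM in shControl replicates 1, 4 and 5. In shSQLE replicates 1, 2 and 5 it held 67.1, 432 and 386 CPM. Gpr37 held 97.1, 105 and 113 CPM in the same shControl libraries, then 120, 19.6 and 21.2 CPM in the shSQLE libraries. The 10 lower genes were higher in shSQLE replicate 1 than in shSQLE replicates 2 and 5 by a median of 2.64 on the log2 scale (1.90 to 3.30). Melanocyte lineage genes, raised alike by a larger share of tumour cells, differed by 0.16 (quartiles -0.22 and 0.33). For the 21 higher genes the median was -2.25, against -1.48 for macrophage, fibroblast and endothelial markers. Both sets were picked from a fit that left shSQLE replicate 1 out, so a wide gap can follow from the choice. Less host tissue in shSQLE replicate 1 therefore stays open for both. A wrong label of shSQLE replicate 1 is argued against by its Sqle level of 70.4 CPM. Of 10 splits of the 5 libraries 1, the real one, gave as many genes (31, highest other 0), too few splits for a share under 0.05. This fit was taken up because it alone among the fits that left out 1 library gave calls, which favours the real split. It remains possible that the shSQLE tumours came from cells that differed, such as separate knockdown derivatives, which was not tested.

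Other splits of the 6 libraries were also counted for the whole comparison, where 10 splits are too few for a share under 0.05. All 10 gave as many genes past the edgeR threshold (0 in the real split, highest other 0), which a real count of 0 fixes beforehand, so that count tests nothing. At an unadjusted p under 0.05, 6 of 10 gave as many genes (413 in the real split, highest other 2170), and the split of shControl replicates 1 and 5 with shSQLE replicate 2 from the other 3 libraries, which gave 2170, points to a structure of the samples other than the groups. Of the 10 splits, 2 gave as many called lists (17 in the real split, highest other 21).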
